A study of Arabidopsis thaliana with 6 samples.

How the data were processed

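Messenger RNA was sequenced from etiolated Arabidopsis thaliana seedlings in 6 libraries, 2 biological repeats each of Col-0 on MS (Col_MS), Col-0 on MS with kynurenine (Col_Kyn) and a wei8 tar2 line on MS (wei8tar2_MS). Per the labels' protocols, seeds were imbibed at 4 °C for 3 days, kept in the light for a few hours and then grown for 3 days in darkness at 22 °C, and kynurenine was supplied in the growth medium. Per the labels' protocols, total RNA was extracted, mRNA was fragmented and converted to double-stranded cDNA with random hexamers, and adaptor-ligated fragments were amplified by PCR. No step in that description marks strand. Per the labels, the line is homozygous for wei8 and heterozygous for tar2, and they do not say which seedlings of its progeny were pooled.

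Reads were aligned with TopHat 1.3.0 to TAIR10, per the submitters' processing notes. Each deposited table gives per gene the number of uniquely mapped reads, as raw counts per the file headers. In the same deposited tables the authors gave RPKM values, that is the count divided by the listed gene length in kilobases and by the header's total. The sums of the counts equal the header totals, and the RPKM values recomputed from counts, lengths and totals differed from the deposited ones by no more than a relative 8.48e-14. The smallest listed count is 1 in every table, and genes with no read are not listed and were taken as 0. The program that counted the reads, its strand setting and the annotation release are not given in the sources used here. All tests below were computed from the counts, and RPKM served for this check alone.

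Library totals were 26753309 and 28243135 reads for Col_MS, 31817638 and 18143395 for Col_Kyn, and 26943103 and 25129503 for wei8tar2_MS, with 23510 to 24243 genes listed per library. A count of 0 allows up to 3 reads, which is 0.0943 to 0.165 CPM according to the library. Intervals and floors cover counting error only, since PCR copies were not told apart. The 10 most counted genes took 6.97% to 8.12% of the reads, ribosomal RNA genes 2.26% to 2.97% and mitochondrial genes 0.296% to 0.395%. No library was a copy of another: replicates differed beyond sampling, with chi-square values per degree of freedom of 39.1 for Col_MS, 28.7 for Col_Kyn and 5.27 for wei8tar2_MS. Of 20182 tested genes with at least 100 reads in all, 125 had counts identical to those of another gene in all 6 libraries and are uncertain where named.

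Symbols and coordinates came from the TAIR10.1 RefSeq annotation. The deposited tables hold locus names and no coordinates, and were matched to this annotation by locus name. Printed coordinates are those of TAIR10.1, an update of the TAIR10 assembly in the notes, and no coordinates were converted. Of 26185 loci with a read in at least 1 library, 25911 were found there, 23961 of them protein coding, and 22225 were listed in all 6 libraries.

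Groups were taken from the labels. The counts were fitted in R 4.3.3 with edgeR 4.0.16, using TMM factors (0.964 to 1.03), which also scale the CPM values printed, filterByExpr by group, which left 21326 genes, and the quasi-likelihood F-test on all 6 libraries with 1 coefficient per group. Genes are called at a Benjamini-Hochberg adjusted p under 0.05, and standard errors are the log2 fold change divided by the square root of F. Kynurenine and wei8tar2 were each compared with Col_MS and with each other. The names of the groups carry the replicate numbers 1 and 2 but no shared day, and deviations from the group means correlated between equal numbers at 0.202, 0.0220 and -0.0390. Samples were therefore not paired in the main fit, although these values do not settle whether equal numbers were handled together.

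Gene lists were written and fixed, with the tests and alternatives, before the data were examined. The 23 lists hold 354 loci, of which 349 had a read, and cover IAA biosynthesis, tryptophan biosynthesis, the indole glucosinolate and camalexin pathway, Aux/IAA, GH3, SAUR and other auxin-responsive genes, auxin transport, ethylene biosynthesis, ethylene perception and response, root meristem, stem cell and root cap, root hair, and xylem and secondary wall markers, cell cycle, photosynthesis and chlorophyll, seed storage and reserve, xenobiotic detoxification, defence, jasmonate-responsive, type-A cytokinin response regulator, brassinosteroid and gibberellin biosynthesis, heat shock and reference genes. They were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 23 lists, and again with the correlation estimated per list and with fry, which asks whether the genes of a list move one way on balance. In the direct comparison the list test was added after the data were examined. A further 5 lists, of circadian clock, sugar-starvation and dark-inducible, ribosome biogenesis, iron-uptake and mature root tissue genes, were written after gene values had been seen and appear in the closing section.

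Genes were named by a rule fixed with the lists. It takes TAA1, TAR1 and TAR2 in every library; per comparison the 8 called genes with the largest rise and the 8 with the largest fall among those whose libraries do not overlap, with a mean log2 CPM of at least 2 and a symbol of their own; from each fixed list up to 4 members with the smallest p in each comparison with Col_MS, called or not; and 6 genes per direction called the same way in both. Reference genes are given as a range. MRD1, AT4G20690 and AT5G14840 fall outside this rule.

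The overlap of the comparisons with Col_MS was set against 40 simulated data sets without effects that share the control libraries. The tests were tried on simulated counts for Col_Kyn against Col_MS with 21326 genes, of which 50 were changed at each of 4 fold sizes. Of these edgeR recovered 14 at 1.5-fold, 40 at 2-fold, and 50 at 4-fold and 50 at 8-fold, and it called 9 of 21126 unchanged genes. DESeq2 recovered 13, 39, 50 and 50 and called 10 unchanged genes, and limma-voom recovered 14, 40, 50 and 50 and called 8. The changed genes were drawn from those with a mean of at least 2 CPM. Each gene's spread followed a trend on its level and was equal in all groups, unlike in the data. There edgeR called 78 genes with kynurenine and DESeq2 750. The recovery therefore checks the tests and does not give their power in these data.

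Alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, no filter on low counts, a filter of at least 10 CPM in 2 libraries, a 2-fold minimum, an adjusted p under 0.01, fits on the compared groups alone, the replicate number as a block, the omission of each library in turn, and comparisons against different Col_MS libraries. Tests of outliers among replicates and of other splits of the samples were left out, since groups of 2 libraries are too small for them.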

Results

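The series measured messenger RNA by sequencing in etiolated seedlings of Arabidopsis thaliana, which were grown for 3 days in darkness at 22 °C after the seeds had been imbibed in the cold and briefly exposed to light. The 6 libraries form 3 groups of 2 biological repeats each. Col_MS is the wild-type accession Col-0 on MS, a standard mineral medium for plant culture. Col_Kyn is Col-0 on MS to which kynurenine was added, at a concentration that the labels give as 25 mM, a unit that could not be checked from the sources used here. Kynurenine, in its L form, is known as an inhibitor of the tryptophan aminotransferases TAA1 and TAR, which make indole-3-pyruvic acid from tryptophan on the main route to indole-3-acetic acid (IAA), the principal natural auxin. wei8tar2_MS is a line on MS with mutations in WEI8, another name of TAA1, and in TAR2, of which the labels give the latter as heterozygous. The title of the series names seedlings deficient in IAA biosynthesis as its subject, and the comparisons asked which transcripts changed when the pathway was impaired by the compound or by the mutations, and where these differed.

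Uniquely mapped reads summed to 26753309 and 28243135 in the Col_MS libraries, to 31817638 and 18143395 in the Col_Kyn libraries and to 26943103 and 25129503 in the wei8tar2_MS libraries, in the order of replicates 1 and 2. Levels below are CPM, the counts scaled by edgeR to a common library size with TMM factors, given as mean ± SD with n = 2 libraries per group, and log2 fold changes are given with their standard errors. Replicates of the wei8tar2_MS group lay closest together, with 255 genes more than 2-fold apart, against 986 for Col_Kyn and 1090 for Col_MS. On the principal component that carried 46.8% of the variance, Col_MS replicate 1 lay at -62.8 and Col_MS replicate 2 at -19.5, while the other 4 libraries lay between 3.29 and 30.8. Genes of the camalexin pathway, which makes an indolic defence compound, were among those that differed within Col_MS. CYP71A12 stood at 94.9 CPM in replicate 1 and 0.351 in replicate 2, and PAD3 at 62.5 and 1.23.

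Of the genes of the targeted enzymes, TAA1 and TAR2 were read in every library. TAA1 (AT1G70560, chromosome 1, 26604855 to 26607652 in the TAIR10.1 annotation) had 37.9 and 38.7 CPM in Col_MS, 38.4 and 41.5 in Col_Kyn, and 7.90 and 8.36 in wei8tar2_MS. It fell in wei8tar2 (log2 fold change -2.24 ± 0.11, edgeR adjusted p = 0.000562), and its value with kynurenine was 0.06 ± 0.10 (adjusted p = 0.799). TAR2 (AT4G24670, chromosome 4, 12727531 to 12731331) had 10.1 and 8.11 CPM in Col_MS, 7.08 and 6.29 in Col_Kyn, and 2.90 and 2.01 in wei8tar2_MS. It also fell in wei8tar2 (-1.88 ± 0.23, adjusted p = 0.0301), and stood at -0.44 ± 0.21 with kynurenine (adjusted p = 0.349). The call on TAR2 was lost without Col_MS replicate 1 (adjusted p = 0.0713) and without wei8tar2_MS replicate 1 (0.208) or replicate 2 (0.309), whereas that on TAA1 passed without any single library. TAR1, the remaining member of the family, had no read in any library, which allows up to 0.0943 CPM in the deepest library and 0.165 CPM in the shallowest. The counts are of whole genes and do not say where in a gene a mutation lies.

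**Figure D1:**
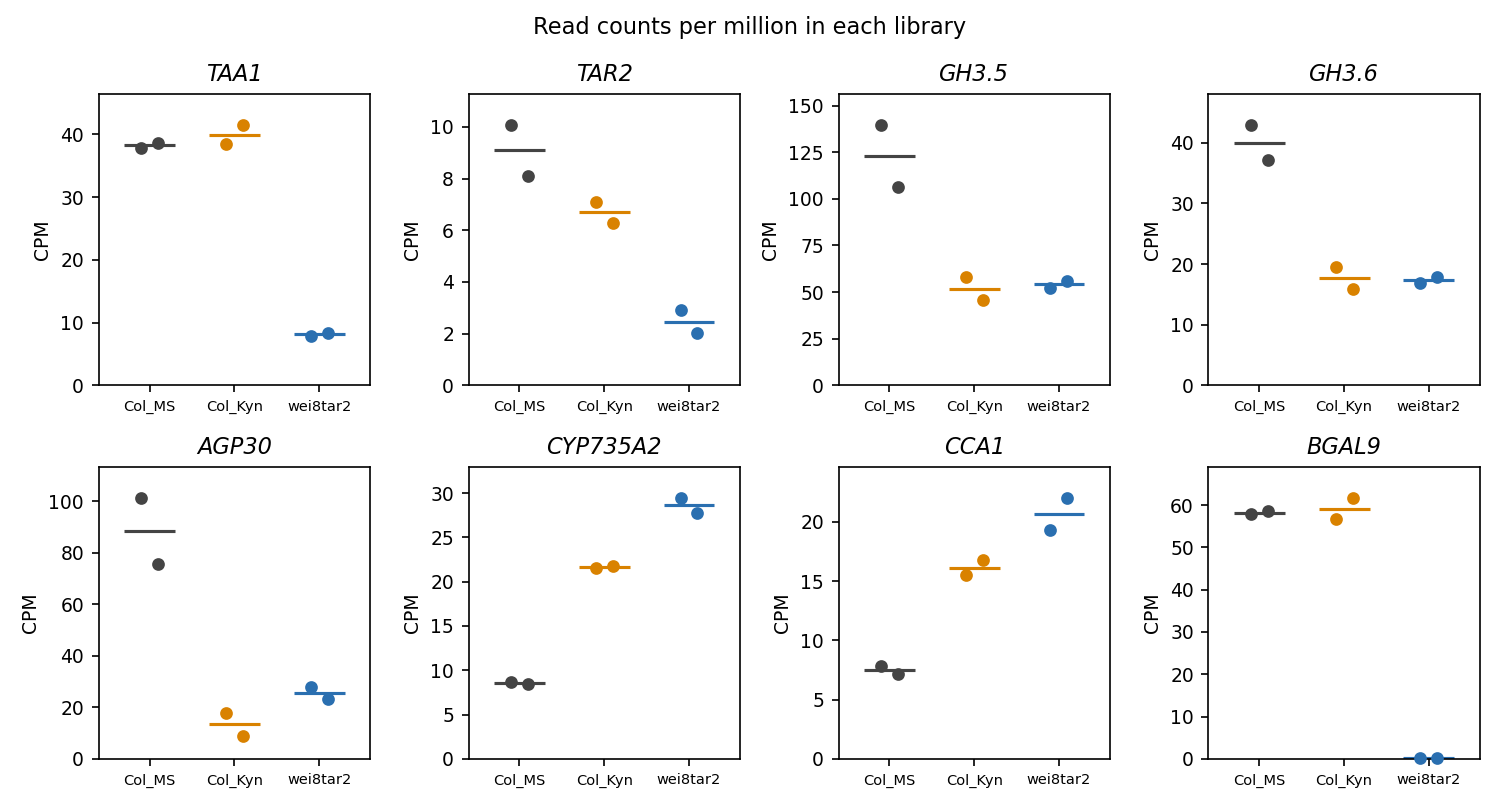
Each panel plots CPM (vertical axis, from 0) of 1 gene in the libraries of Col_MS, Col_Kyn and wei8tar2, with dots for the 2 libraries of a group and a line at their mean. TAA1 stands at 37.9 to 41.5 CPM in the wild-type libraries and at 7.90 and 8.36 in wei8tar2, whereas GH3.6 is lower in both treatments (15.9 to 19.5 CPM) than in Col_MS (37.1 and 43.0).

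The comparison of Col_Kyn with Col_MS asked which transcripts changed when the inhibitor was supplied; neither enzyme activity nor IAA was measured. Both of the auxin-conjugating genes GH3.5 (AT4G27260, chromosome 4, 13653579 to 13656285) and GH3.6 (AT5G54510, chromosome 5, 22130964 to 22133688), which encode enzymes that join IAA to amino acids and are themselves auxin-induced, fell. GH3.5 went from 123 ± 23.6 to 51.8 ± 8.64 CPM (log2 fold change -1.25 ± 0.17, edgeR adjusted p = 0.0414) and GH3.6 from 40.03 ± 4.16 to 17.7 ± 2.55 CPM (-1.18 ± 0.14, adjusted p = 0.0264). Among called genes with a symbol, a mean log2 CPM of at least 2 and libraries that do not overlap, the largest falls were of AGP30 and PRP1. AGP30 (AT2G33790, chromosome 2, 14293561 to 14295353), a root arabinogalactan protein, went from 88.3 ± 18.1 to 13.4 ± 6.25 CPM (-2.69 ± 0.30, adjusted p = 0.0264), and PRP1 (AT1G54970, chromosome 1, 20504901 to 20506504), a proline-rich protein, from 28.1 ± 12.03 to 5.64 ± 0.274 CPM (-2.32 ± 0.29, adjusted p = 0.0310). The calls on GH3.5 and GH3.6 were lost without Col_MS replicate 1 (adjusted p = 0.0802 and 0.0767), without Col_Kyn replicate 1 (0.0709 and 0.0541) or replicate 2 (0.143 and 0.110), and without either of the wei8tar2_MS libraries (0.111 to 0.141). AGP30 lost its call without Col_MS replicate 1 (0.0649) and PRP1 without Col_Kyn replicate 1 (0.106), and both without Col_Kyn replicate 2 (0.0843 and 0.146) or either of the wei8tar2_MS libraries (0.104 to 0.106).

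Of the other named genes that fell with kynurenine, 3 are root genes with symbols of the beta-glucosidase family. BGLU35 (AT1G51470) changed by -2.00 ± 0.23 and BGLU34 (AT1G47600) by -1.83 ± 0.21, both with an edgeR adjusted p of 0.0264, and BGLU21 (AT1G66270), an abundant enzyme of endoplasmic reticulum bodies, went from 233 ± 0.897 to 84.8 ± 11.2 CPM (-1.46 ± 0.13, adjusted p = 0.0217). The cysteine endopeptidase gene CEP2 (AT3G48340) changed by -1.79 ± 0.17 (adjusted p = 0.0217). Among the genes that rose with kynurenine, CYP735A2 (AT1G67110, chromosome 1, 25061673 to 25065446), which encodes the hydroxylase that makes trans-zeatin-type cytokinins, went from 8.56 ± 0.0885 to 21.7 ± 0.207 CPM (1.34 ± 0.11, adjusted p = 0.0215). CYP86A1 (AT5G58860), a hydroxylase of suberin synthesis, stood at 1.71 ± 0.24 (adjusted p = 0.0424), and THAS1 (AT5G48010), the thalianol synthase, at 1.18 ± 0.12 (adjusted p = 0.0264). The other named genes that rose included ERD5 (AT3G30775), a proline dehydrogenase, by 1.64 ± 0.18, TPPF (AT4G12430), a trehalose-phosphate phosphatase, by 1.61 ± 0.18, PP2-A13 (AT3G61060) by 1.46 ± 0.16 and the beta-galactosidase gene BGAL2 (AT3G52840) by 1.43 ± 0.11. The light-stress gene ELIP2 (AT4G14690) rose by 1.3 ± 0.17 (adjusted p = 0.0340). TPPF had the same counts as AT4G12432 in all 6 libraries, so that its reads cannot be assigned between them.

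In all, edgeR called 78 of 21326 tested genes with kynurenine at an adjusted p under 0.05, 31 of them higher and 47 lower, and 70 of the 78 differed at least 2-fold. The unadjusted p was under 0.05 for 3624 genes, and DESeq2 called 750 genes (426 higher), among them all 78. The count was 40 without Col_MS replicate 1 (23 of the 78 were still called), 992 without Col_MS replicate 2, 38 without Col_Kyn replicate 1 (14 still called), and 0 by edgeR without Col_Kyn replicate 2 or without either of the wei8tar2_MS libraries, which enter through the shared estimate of the spread; the genes at an unadjusted p under 0.05 then numbered 3083, 2393 and 2380, and limma-voom on all libraries called 50. Of the 17 named genes called here, 0 kept an adjusted p under 0.05 in these last 3 fits by edgeR, 7 kept it without Col_MS replicate 1 and 5 without Col_Kyn replicate 1.

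Among the auxin lists, only the GH3 genes were called as a group with kynurenine. Of their 6 tested members 5 had negative fold changes, with a median of -1.48 (camera adjusted p = 0.000297, but adjusted p = 0.795 with an estimated correlation). Over all genes 2 members were called, and adjusted over the list alone 5 were lower. GH3.1 stood at -2.27 ± 0.36 (adjusted p = 0.0658) and GH3.2 at -1.71 ± 0.42 (0.136). The Aux/IAA genes, which encode short-lived repressors of auxin responses, had a median of -0.20 over 26 members (camera adjusted p = 0.165), the 41 SAUR genes one of -0.08 (0.981) and the 14 other auxin-responsive genes one of -0.09 (0.139). Without Col_MS replicate 1, in which the Aux/IAA and SAUR genes had lower levels than in replicate 2 (median log2 ratios of -0.27 and -0.44), these 3 lists passed the test as lower (adjusted p = 0.00164, 0.0226 and 0.0106), and the last did so without Col_Kyn replicate 1 as well (0.0398). Without Col_MS replicate 2 their medians were -0.03, 0.16 and 0.00 (adjusted p = 0.737, 0.0620 and 0.737), and that of the SAUR genes was 0.13 without Col_Kyn replicate 1, so that its sign turned. Adjusted over the list alone, 4 members of the other auxin-responsive genes were lower, and 0 of the Aux/IAA and 0 of the SAUR genes by edgeR, of which 2 and 4 had an unadjusted p under 0.05 and 0 and 0 were called by DESeq2 over all genes. HAT2, a homeodomain gene induced by auxin, stood at -0.51 ± 0.11 (adjusted p = 0.116), LBD16 at -0.83 ± 0.25 (0.180) and IAA1 at -0.62 ± 0.23 (0.243). Auxin transport genes had a median of 0.00 and a mean of -0.05 (camera adjusted p = 0.981, 16 members, 1 lower adjusted over the list alone), and the sign of their median turned with the scaling. The 10 measured IAA biosynthesis genes had a median of 0.03 (camera adjusted p = 0.974), its sign turning with the scaling, with YUC8 at 0.76 ± 0.20 (adjusted p = 0.139) and YUC9 at -0.67 ± 0.21 (0.188).

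Lists of root growth zones and of dividing cells were lower as groups with kynurenine. All 7 root hair markers had negative fold changes, with a median of -0.91 (camera adjusted p = 0.000294, and 0.795 with an estimated correlation), and the 7 were lower when adjusted over the list alone. COBL9 stood at -0.92 ± 0.21 (adjusted p = 0.120) and RHD6, a transcription factor that starts root hairs, at -0.91 ± 0.24 (0.148). This list was 0.77 lower, as a median log2 ratio, in Col_MS replicate 1 than in replicate 2, and its median was -0.47 without replicate 2. The root meristem, stem cell and root cap markers had a median of -1.15 with 8 of 10 members negative (camera adjusted p = 0.00151, and 0.746 with an estimated correlation), and 6 were lower and 1 higher when adjusted over the list alone. PLT1, a transcription factor of the root stem cell niche, stood at -2.95 ± 0.63 (adjusted p = 0.107) and the root cap gene SMB at -1.92 ± 0.49 (0.140), both at under 3 CPM in every library. Of 26 cell cycle genes 25 were negative, with a median of -0.30 (camera adjusted p = 1.06e-05, and 0.746 with an estimated correlation), 2 of them lower when adjusted over the list alone. The mitotic cyclin CYCB1;1 stood at -1.07 ± 0.20 (adjusted p = 0.0922). No member of these 3 lists passed the edgeR test over all genes, where 7, 7 and 5 of them had an unadjusted p under 0.05 and 2, 1 and 1 were called lower by DESeq2. Xylem and secondary wall markers had a median of -0.03 (camera adjusted p = 0.752).

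Further lists moved along with the gap between the Col_MS libraries. The seed storage and reserve genes had a median of -1.63 with kynurenine, all 15 members being negative (camera adjusted p = 1.06e-05, and 0.795 with an estimated correlation), and 6 were lower when adjusted over the list alone. Their levels were 1.25 higher, as a median log2 ratio, in Col_MS replicate 1 than in replicate 2, and their median was -0.45 without replicate 1 (adjusted p = 0.0102) and -2.71 without Col_Kyn replicate 1. The oleosin gene OLEO2 stood at -3.55 ± 0.61 (adjusted p = 0.0797), and EM1, a late embryogenesis gene, had no read in Col_Kyn against 1.75 and 0.843 CPM in Col_MS. Tryptophan biosynthesis genes had a median of -0.64 with 10 of 11 members negative (camera adjusted p = 0.00266, and 0.795 with an estimated correlation), 2 of them lower when adjusted over the list alone. PAI1 stood at -0.68 ± 0.16 (adjusted p = 0.123) and PAI2 at -0.64 ± 0.15 (0.126). This list was 0.79 higher in Col_MS replicate 1 than in replicate 2, and without replicate 1 its median was -0.13 and it was no longer called (0.210). Heat shock genes (gap 1.06, median -0.63, camera adjusted p = 0.185), the indole glucosinolate and camalexin pathway (gap 0.64, median -0.42, 0.139), xenobiotic detoxification genes (gap 0.56, median -0.37, 0.0523) and defence genes (gap 0.27, median -0.61, 0.272) were not called. They passed the test as lower without Col_MS replicate 2, with adjusted p of 0.00901, 5.19e-05, 4.08e-06 and 0.0444, and the detoxification genes also without either of the wei8tar2_MS libraries (0.0384 each). Without Col_MS replicate 1 the medians of these 4 lists were 0.08, 0.01, 0.07 and -0.10 (adjusted p = 0.965 each). The fold change of GSTF6, a glutathione transferase, was -2.89 ± 1.03 (adjusted p = 0.229) with 563 and 30.9 CPM in the Col_MS libraries, and that of WRKY33 was -1.01 ± 0.40 (0.269). Adjusted over the list alone, 1 heat shock gene was lower.

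The remaining lists were not called with kynurenine. The medians were 0.06 for ethylene biosynthesis (camera adjusted p = 0.981, mean -0.19, 1 member lower adjusted over the list alone, its sign turning with the scaling), -0.15 for ethylene perception and response (0.453), 0.08 for jasmonate-responsive genes (0.503), -0.10 for brassinosteroid and gibberellin biosynthesis (0.981, 1 lower adjusted over the list alone, and a median of 0.09 without Col_MS replicate 2) and 0.26 for the type-A cytokinin response regulators (0.139). The last of these, 0.42 lower in Col_MS replicate 1 than in replicate 2, passed as higher without Col_MS replicate 2 (0.00901). The jasmonate-responsive genes, 0.71 lower in Col_MS replicate 1 than in replicate 2, had a median of 0.48 without Col_MS replicate 2, 0.56 without Col_Kyn replicate 1 and -0.21 without Col_Kyn replicate 2. GA20OX2, a gibberellin oxidase gene, stood at -1.30 ± 0.26 (adjusted p = 0.0976) and ARR7 at 0.66 ± 0.20 (0.189). Photosynthesis and chlorophyll genes had a median of 0.18 over 27 members (camera adjusted p = 0.272), but the Col_Kyn libraries differed in them. Without Col_Kyn replicate 1 the median was 0.71 (adjusted p = 4.13e-14) and without replicate 2 it was -0.57 (1.83e-07). LHCB1.4 had 1.51 and 18.5 CPM in Col_Kyn, and ELIP2 was the list's called member. Fold changes of the 10 reference genes ranged between -0.26 and 0.60, with no member called by edgeR (3 at an unadjusted p under 0.05, 1 called by DESeq2). No list was called by fry (lowest adjusted p 0.0961, 3 lists at an unadjusted p under 0.05).

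The comparison of wei8tar2_MS with Col_MS asked the same of the mutations. The auxin-conjugating genes GH3.5 and GH3.6 fell here as well, and CYP735A2 and ASN1 rose. GH3.5 went from 123 ± 23.6 to 54.1 ± 2.81 CPM (log2 fold change -1.19 ± 0.17, edgeR adjusted p = 0.0405) and GH3.6 from 40.03 ± 4.16 to 17.38 ± 0.688 CPM (-1.20 ± 0.14, adjusted p = 0.0252). CYP735A2 rose to 28.6 ± 1.14 CPM (1.74 ± 0.11, adjusted p = 0.00182), and ASN1 (AT3G47340), an asparagine synthetase induced in darkness, from 57.9 ± 11.03 to 195 ± 5.09 CPM (1.75 ± 0.23, adjusted p = 0.0360). BGAL9 (AT2G32810, chromosome 2, 13919127 to 13925421), a beta-galactosidase gene, was nearly absent, at 0.154 ± 0.0615 CPM against 58.2 ± 0.435 in Col_MS (-8.53 ± 0.20, adjusted p = 6.21e-06). GH3.5, GH3.6 and ASN1 lost their calls without Col_MS replicate 1 (adjusted p = 0.0771, 0.0574 and 0.0846), and these genes and CYP735A2 lost them without wei8tar2_MS replicate 1 (0.0890 to 0.456) or replicate 2 (0.0646 to 0.309), while BGAL9 was called without any single library.

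Other named genes that rose in wei8tar2 included the root iron transporter gene IRT1 (AT4G19690, 2.18 ± 0.30, edgeR adjusted p = 0.0405), the dehydrin gene LTI30 (AT3G50970, 2.15 ± 0.36, adjusted p = 0.0475) and the endoglucanase gene GH9B18 (AT4G39010, 1.71 ± 0.28, adjusted p = 0.0461). HEI10 (AT1G53490) was also called higher, on reads that cannot be told apart from those of an overlapping gene, as described with the direct comparison. The transposable element SADHU3-2 (AT3G42658, 1.58 ± 0.24, adjusted p = 0.0419) and LBD25 (AT3G27650), a gene of the lateral organ boundaries family (1.47 ± 0.18, adjusted p = 0.0301), rose too. Those that fell included PRP1 (-2.37 ± 0.29, adjusted p = 0.0301), the cytochrome P450 gene CYP96A3 (AT1G65340, -2.28 ± 0.34, adjusted p = 0.0419) and MLS (AT5G03860), the malate synthase of the glyoxylate cycle (-2.12 ± 0.30, adjusted p = 0.0407). Falls were also called for MSL9 (AT5G19520), a mechanosensitive channel of roots (-1.83 ± 0.27, adjusted p = 0.0407), and AGP30 (-1.79 ± 0.29, adjusted p = 0.0461). Genes named above for kynurenine also passed here, with a rise of THAS1 (0.83 ± 0.12, adjusted p = 0.0407) and falls of CEP2 (-1.01 ± 0.17, adjusted p = 0.0461) and BGLU21 (-0.82 ± 0.13, adjusted p = 0.0440). Apart from HEI10 and PRP1, all genes of this paragraph lost their calls without Col_MS replicate 1 and without either of the wei8tar2_MS libraries. PRP1 lost its call without either of the wei8tar2_MS libraries. None of these fold changes turned its sign in those fits.

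The test by edgeR called 230 of 21326 genes in wei8tar2, 120 higher and 110 lower, and 148 of them differed at least 2-fold; 4398 had an unadjusted p under 0.05, DESeq2 called 1333 and limma-voom 216. The count was 51 without Col_MS replicate 1 (33 of the 230 were still called), 1644 without Col_MS replicate 2, 401 without Col_Kyn replicate 1, 5 without wei8tar2_MS replicate 1 and 4 without wei8tar2_MS replicate 2. Of the 33 named genes called here, 10 stayed called without Col_MS replicate 1, and 5 and 4 without replicate 1 or 2 of wei8tar2_MS.

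The GH3 genes were again the auxin list that was called as a group, with all 6 members negative and a median of -1.32 (camera adjusted p = 0.000771, and 0.810 with an estimated correlation). As with kynurenine, 2 members were called over all genes and 5 were lower when adjusted over the list alone. GH3.3 stood at -2.44 ± 0.53 (adjusted p = 0.0734). Medians were -0.08 for the Aux/IAA genes (camera adjusted p = 0.413), 0.04 for the SAUR genes (0.643), -0.10 for other auxin-responsive genes (0.383, 1 lower adjusted over the list alone) and 0.02 for auxin transport (0.974, mean -0.05). The Aux/IAA genes passed as lower without Col_MS replicate 1 (0.00870) and had a median of 0.07 without replicate 2, and the SAUR genes passed as higher without Col_MS replicate 2 (0.0232) and had a median of -0.14 without replicate 1. HAT2 stood at -0.50 ± 0.11 (adjusted p = 0.0762) and IAA26 at -0.52 ± 0.15 (0.114). Among the IAA biosynthesis genes, TAA1 and TAR2 fell, while the median of the 10 was 0.29 and their mean -0.06 (camera adjusted p = 0.543). Adjusted over the list alone, 2 members were lower and 2 higher. YUC8, a flavin monooxygenase that acts after the aminotransferases, stood at 0.91 ± 0.19 (adjusted p = 0.0702) and YUC6 at 0.47 ± 0.15 (0.141).

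Cell cycle genes were lower as a group in wei8tar2, with all 26 members negative and a median of -0.39 (camera adjusted p = 7.2e-07, and 0.810 with an estimated correlation), 5 of them lower when adjusted over the list alone. CYCB1;1 stood at -0.95 ± 0.20 (adjusted p = 0.0699) and the kinesin gene HIK at -0.51 ± 0.12 (0.0830). All 7 root hair markers were negative, with a median of -0.64 (camera adjusted p = 0.0121, and 0.810 with an estimated correlation) and 3 lower when adjusted over the list alone; without Col_MS replicate 2, in which this list was 0.77 higher than in replicate 1, the median was -0.18 and the list was not called (0.176). PRP3 stood at -0.99 ± 0.24 (adjusted p = 0.0828). Root meristem and cap markers had a median of -0.75 (camera adjusted p = 0.0982, or 0.0308 without Col_MS replicate 2), which was -0.42 without Col_MS replicate 1 (0.156), with 4 lower and 2 higher when adjusted over the list alone. Tryptophan biosynthesis genes were negative in 11 of 11 members with a median of -0.61 (0.00407, and 0.810 with an estimated correlation), and this was lost without Col_MS replicate 1 (median -0.23, 0.150), in which the list stood 0.79 higher than in replicate 2. PAI1 stood at -0.61 ± 0.15 (adjusted p = 0.0910). No member of these 4 lists was called over all genes by edgeR, where 12, 4, 6 and 6 had an unadjusted p under 0.05 and 1, 1, 1 and 0 were called by DESeq2.

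As groups, the type-A cytokinin response regulators and the photosynthesis genes were higher in wei8tar2. The former, which are induced by cytokinin, had 7 of 8 positive members and a median of 0.61 (camera adjusted p = 0.0121, and 0.810 with an estimated correlation), and 3 were higher when adjusted over the list alone. ARR4 stood at 0.72 ± 0.15 (adjusted p = 0.0697), ARR7 at 0.84 ± 0.20 (0.0828) and ARR5 at 0.50 ± 0.14 (0.117). The list was 0.42 lower in Col_MS replicate 1 than in replicate 2 and was lost without replicate 1 (median 0.38, 0.150). Photosynthesis and chlorophyll genes were positive in 22 of 27 members, with a median of 0.32 (camera adjusted p = 0.0153, and 0.810 with an estimated correlation), and were lost without Col_MS replicate 1 (0.104). ELIP2 rose by 1.37 ± 0.17 (adjusted p = 0.0301), ELIP1 stood at 1.92 ± 0.34 (0.0511), and 2 members were higher when adjusted over the list alone.

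The other lists were not called in wei8tar2. Reserve genes had a median of -0.45 (camera adjusted p = 0.192, 4 lower adjusted over the list alone), with MLS fallen and ICL, its partner in the glyoxylate cycle, at -2.15 ± 0.42 (adjusted p = 0.0649). They passed as lower without Col_MS replicate 2 (0.00337) and without wei8tar2_MS replicate 1 (0.0262), but their median was 0.65 without Col_MS replicate 1 (0.873) and -0.23 without wei8tar2_MS replicate 2 (0.528). Detoxification genes had a median of -0.17 (0.814), and passed as higher without Col_MS replicate 1 (0.00573) and as lower without replicate 2 (0.00198). GSTU20, a glutathione transferase, fell by 1.01 on the log2 scale (SE 0.14, edgeR adjusted p = 0.0405). Indole glucosinolate and camalexin genes had a median of -0.47 (0.314, 2 higher and 4 lower adjusted over the list alone) and passed as lower without Col_MS replicate 2 (0.000574), whereas their median was 0.02 without Col_MS replicate 1 (0.829). Xylem markers had a median of 0.14 with 10 of 10 positive (0.101, and 0.0491 without wei8tar2_MS replicate 2). Medians were -0.12 for heat shock genes (0.814, with a median of 0.34 without Col_MS replicate 1 and -0.53 without replicate 2), -0.44 for defence genes (0.714, with a median of -0.06 without Col_MS replicate 1) and 0.17 for jasmonate-responsive genes (0.383, with a median of -0.01 without Col_MS replicate 1 and 0.77 without replicate 2). They were -0.15 for ethylene perception and response (0.192), 0.20 for ethylene biosynthesis (0.695, mean -0.52) and 0.21 for brassinosteroid and gibberellin biosynthesis (0.413, mean -0.04). ACS9, an ethylene biosynthesis gene, was called lower with 0.946 and 1.34 CPM in Col_MS and a single read or none in the wei8tar2_MS libraries. Reference genes ranged between -0.41 and 0.45, with none called by edgeR, 2 at an unadjusted p under 0.05 and 2 called by DESeq2. No list was called by fry (lowest adjusted p 0.120, 5 lists at an unadjusted p under 0.05).

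**Figure D2:**
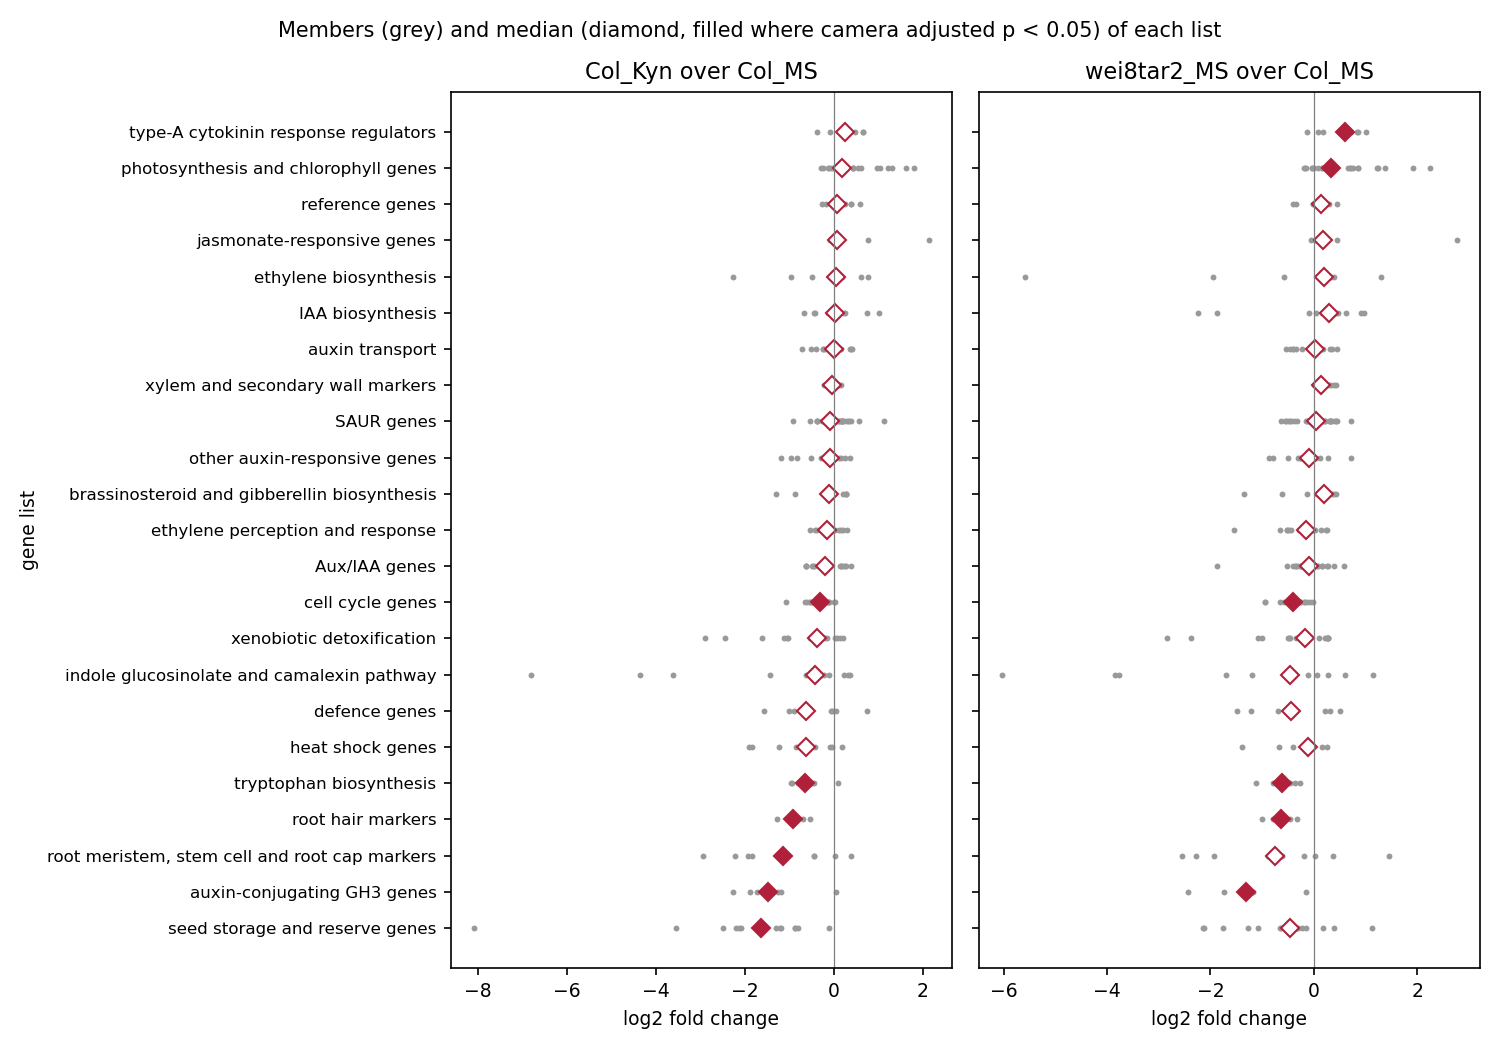
Log2 fold changes (horizontal axes) of the members of each of 23 gene lists (vertical axis, grey dots) with kynurenine, left, and in wei8tar2, right, both against Col_MS, with a diamond at the median, filled where the camera adjusted p with the preset correlation is under 0.05. Medians of the GH3 genes lie at -1.48 and -1.32 and those of the cell cycle genes at -0.30 and -0.39.

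Some genes were called in the same direction with kynurenine and in wei8tar2, each compared with the same Col_MS libraries. In these comparisons 52 genes were called the same way, 22 higher and 30 lower, and 0 were called in opposite directions. Shared controls favour equal signs, so the 0 is not separate evidence of a like effect. Among genes with a symbol, a mean log2 CPM of at least 2 and libraries that do not overlap, those with the largest shared falls were PRP1, AGP30, BGLU35, BGLU34, GH3.6 and GH3.5, of which BGLU35 and BGLU34 stood at -1.47 ± 0.22 and -1.33 ± 0.21 in wei8tar2 (edgeR adjusted p = 0.0419 and 0.0440). By the same criteria the largest shared rises were of BGAL2 (1.36 ± 0.11 in wei8tar2, adjusted p = 0.00794), CYP735A2, ELIP2, TPPF (1.23 ± 0.18, adjusted p = 0.0407), PP2-A13 (1.13 ± 0.16, adjusted p = 0.0405) and CCA1 (AT2G46830), a transcription factor of the circadian clock, which rose by 1.1 ± 0.14 with kynurenine (adjusted p = 0.0310) and by 1.45 ± 0.14 in wei8tar2 (adjusted p = 0.0117).

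Because both comparisons use the same Col_MS libraries, part of this overlap may arise from them. Lists drawn independently with the observed sizes would share 0.174 higher and 0.242 lower genes, which leaves out the shared controls. In 40 simulated data sets with no effect at most 1 gene was called in either comparison and 0 in both, so that the simulations do not say how many of the 52 the shared controls could give. Across genes, which are not independent replicates, the fold changes correlated with r = 0.740, against 0.493 (0.478 to 0.508) in the simulated data. Their covariance was 0.210 against a simulated 0.0422, a difference of 0.167. The simulations gave all groups the same spread. In the data the median absolute log2 ratio of replicates was 0.217 in Col_MS, 0.196 in Col_Kyn and 0.109 in wei8tar2_MS. Shared controls that vary more than the other groups can give a higher r and covariance without effects, so the simulated ranges do not bound what the controls give. On the log2 CPM scale the observed covariance was 0.166, and the measured spread between the Col_MS libraries alone would give 0.0643. With each comparison set against a different Col_MS library, r was 0.361 or 0.378. With 2 control libraries the controls could not be split into groups with replicates. The count of 52 was 24 without Col_MS replicate 1, 824 without Col_MS replicate 2, and 0 by edgeR without Col_Kyn replicate 2 or either of the wei8tar2_MS libraries, where kynurenine gave no call although 2380 to 3083 genes had an unadjusted p under 0.05; DESeq2 on all 6 libraries gave 514 and limma-voom 39.

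**Figure D3:**
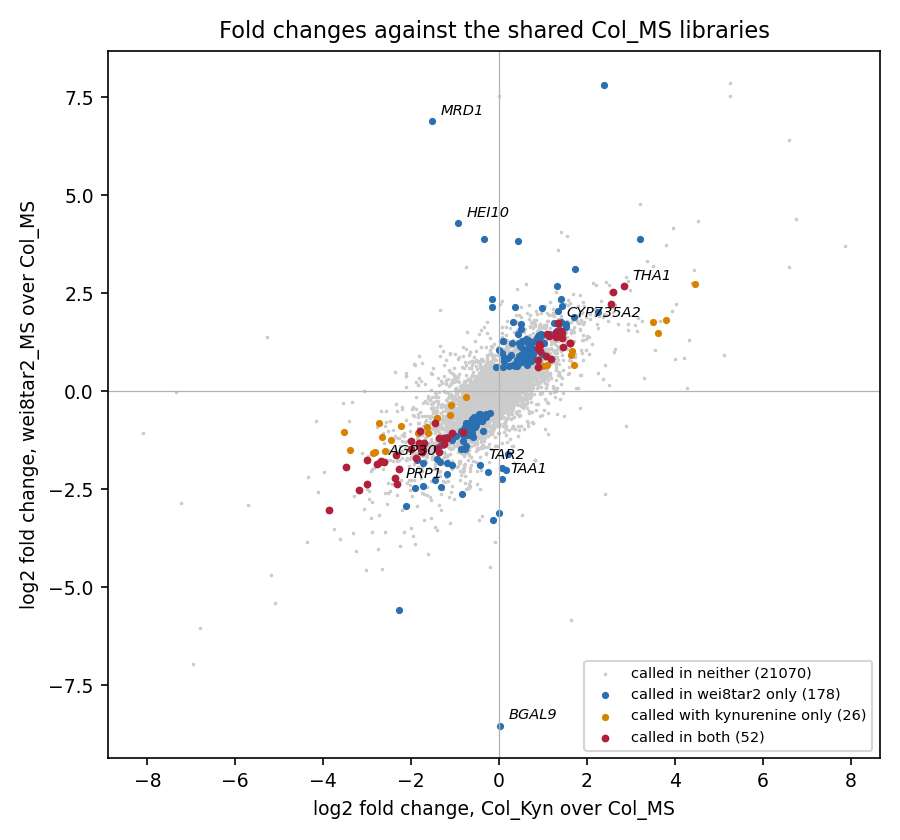
Each point is a tested gene, with its log2 fold change with kynurenine on the horizontal axis and in wei8tar2 on the vertical axis, both against the same Col_MS libraries, and colours mark the genes called in neither, either or both comparisons. The 52 genes called in both lie in the quadrants of equal sign, whereas BGAL9 and TAA1 lie near the vertical axis.

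In the direct comparison of wei8tar2 with kynurenine few genes were called, which does not show that the others were equal. The edgeR test called 6 of 21326 genes, 2 higher and 4 lower in wei8tar2, with 921 at an unadjusted p under 0.05. DESeq2 called 58 genes and limma-voom 6. TAA1 was lower by a log2 fold change of -2.30 ± 0.11 (adjusted p = 0.000473), whereas TAR2 stood at -1.44 ± 0.23 (0.269). BGAL9 was lower by -8.56 ± 0.20 (adjusted p = 6.13e-06), at 0.110 and 0.197 CPM in wei8tar2_MS against 56.7 and 61.6 in Col_Kyn. HEI10, which encodes a RING-finger protein of meiotic crossover formation, was higher by 5.21 ± 0.20 (adjusted p = 0.000130), at 38.7 and 37.0 CPM against 0.929 and 1.14. The other 3 genes fall outside the rule for named genes and were chosen after their values were seen. MRD1 (AT1G53480) had 37.7 and 35.6 CPM in wei8tar2_MS, 0.0961 and 0.114 in Col_Kyn and 0.510 and 0.105 in Col_MS (adjusted p = 0.000602). AT4G20690 (chromosome 4, 11097242 to 11098024) had 1.80 and 1.46 CPM against 13.5 and 14.5 (adjusted p = 0.00128), and the pseudogene AT5G14840 (chromosome 5, 4798329 to 4800738) 33.1 and 33.8 CPM against 135 and 141 (adjusted p = 0.00128). The annotated spans of MRD1 (chromosome 1, 19963047 to 19964712) and HEI10 (19963267 to 19966952) overlap by 1446 bp on opposite strands, and the library preparation described in the labels does not mark strand. HEI10 minus MRD1 came to 1.63 ± 0.117 CPM in Col_MS, 0.932 ± 0.139 in Col_Kyn and 1.24 ± 0.251 in wei8tar2_MS. The reads gained in wei8tar2 were thus nearly the same number in both genes and cannot be told apart. A gain in HEI10 outside the overlap would have raised this difference, unless MRD1 gained as many reads outside it. The values therefore give no sign of a rise of HEI10 apart from MRD1, and the calls on the pair are not separate. The count was 17 without Col_MS replicate 1 and 12 without Col_MS replicate 2; AT5G14840 lost its call without either of the wei8tar2_MS libraries (adjusted p = 0.0963 and 0.0884) and AT4G20690 without replicate 2 (0.0586).

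GH3.5 and GH3.6 did not differ detectably between wei8tar2 and kynurenine, with log2 differences of 0.06 ± 0.17 and -0.03 ± 0.14 (edgeR adjusted p = 1.00 for both). A camera test of the fixed lists on this comparison, added after the data were examined, called 4 lists as higher in wei8tar2, all 4 with an adjusted p of 0.789 or 0.887 with an estimated correlation. The reserve genes differed by a median of 0.98 (adjusted p = 0.000430, or 0.287 without Col_Kyn replicate 2) and the xylem markers by 0.20 with 10 of 10 positive (0.00259, or 0.141 without Col_Kyn replicate 1 and 0.124 without wei8tar2_MS replicate 1). Detoxification genes differed by 0.17 (0.0326) and were lost without any single library of Col_Kyn or wei8tar2_MS (0.0716 to 0.240). Photosynthesis genes differed by 0.10 (0.0492), but were lower in wei8tar2 without Col_Kyn replicate 1 and higher without Col_Kyn replicate 2. Their direction thus depended on which Col_Kyn library was kept. Medians of the list against the mean of the 6 libraries were -0.62 and 0.60 in Col_Kyn, and 0.20 and 0.25 in wei8tar2_MS. The call was lost without Col_MS replicate 1 or 2 and without wei8tar2_MS replicate 2. The GH3 genes differed by a median of 0.02 (0.848), the cell cycle genes by -0.05 (0.214) and the root hair markers by 0.28 (0.117). Lists that gained a call as higher in wei8tar2 were the GH3 genes without Col_Kyn replicate 1 (0.0190), and the root hair markers, the type-A response regulators and the heat shock genes without Col_MS replicate 1 (0.0420, 0.0270 and 0.0319) or replicate 2 (0.0435, 0.0306 and 0.0379).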

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

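Beside the 78, 230, 6 and 52 genes changed by kynurenine, in wei8tar2, between these, and the same way by both, DESeq2 gave 750, 1333, 58 and 514, no filter on low counts 409, 1113, 26 and 295, and the replicate block 130, 367, 12 and 86; the cause was not tested. The labels do not say that equal replicate numbers pair the samples, and deviations that correlated at 0.202 or less do not settle it. At least 10 CPM in 2 libraries, which tests fewer genes, gave 31, 101, 6 and 15, limma-voom 50, 216, 6 and 39, a 2-fold minimum 70, 148, 6 and 42, and an adjusted p under 0.01 0, 11, 6 and 0. Fits on only the 2 groups compared gave 0, 365, 11 and 0. These fits had equally few libraries, so the number of libraries alone does not account for the 0 with kynurenine. That fit left out wei8tar2_MS, whose replicates lay closest. Their median absolute log2 ratio was 0.109, against 0.217 in Col_MS and 0.196 in Col_Kyn. The 78 calls thus drew on a spread shared with a group outside that comparison. Where edgeR gave 0 for kynurenine, 3624 and 2399 genes had an unadjusted p under 0.05. RLE factors gave 75, 228, 6 and 51 and upper-quartile factors 73, 216, 6 and 49. No gene called at first was called in the opposite direction under these alternatives.

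Leaving out a library gave 0 to 992 genes for kynurenine, 4 to 1644 for wei8tar2, 4 to 17 between them and 0 to 824 for both; the highest for all but the direct comparison came without Col_MS replicate 2. The lone library of a group was assumed to vary like the others. The 78 and 230 genes all kept their calls without Col_MS replicate 2, but 23 and 33 without Col_MS replicate 1. Why was not tested.

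The correlation of 0.740 ranged from 0.583 to 0.850 when a library was left out, and was 0.361 and 0.378 against different Col_MS libraries; the latter share no control but rest on 1 library each. It was 0.813 with at least 10 CPM and 0.731 with the block.

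Fixed lists numbered 6 in each comparison. With an estimated correlation 0 and 0 were called (0 and 1 at an unadjusted p under 0.05), by fry 0 and 0 (3 and 5 unadjusted), against 7 and 8 at an unadjusted p by camera. Leave-outs gave 7 to 11 and 5 to 10. The block gave 7 and 6, and at least 10 CPM 4 and 6. Of the 12 calls, 8 kept theirs without Col_MS replicate 1 and 11 without replicate 2, and 12 without any other library. Among 1791 comparisons of named genes called under neither setting, 54 changed sign.

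Alternatives planned for normalized values (pseudocount, filter on values, scaling) were not run, because the tables hold counts. Depth limits genes of a few reads, such as PLT1, EM1 and ACS9.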

Other observations

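The 5 added gene lists and the tests in this part were chosen after the results were seen. For the tests of copy gain and of gene length and GC content alone, the prediction was written before the value of that test was seen. The patterns they address came from the results as well.

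Lists of genes for functions seen among the called genes were tested with camera and adjusted over the 5 lists, and since some of their members prompted them they are not independent evidence. Sugar-starvation and dark-inducible genes had a median of 0.58 with kynurenine and 0.67 in wei8tar2, with 14 of 15 members positive in each (adjusted p = 4.65e-08 and 5.13e-08, but 0.168 and 0.144 with an estimated correlation). Ribosome biogenesis genes had medians of -0.56 and -0.60, with 12 of 12 negative in each (4.26e-07 and 5.69e-07, or 0.217 and 0.205 estimated). In wei8tar2 edgeR called 2 of these lower, and with kynurenine 0, where 10 had an unadjusted p under 0.05, DESeq2 called 5 and limma-voom 0. Circadian clock genes were mixed, with medians of 0.18 and 0.09 (0.00563 and 0.00774, or 0.168 and 0.144 estimated). CCA1 and LHY were called higher in both comparisons and RVE1 in wei8tar2. Iron-uptake genes had medians of 0.25, with 7 of 13 positive, and 0.52, with 10 of 13 positive (0.0287 and 0.000553, or 0.217 and 0.144 estimated). Mature root tissue markers had medians of 0.56 and 0.57, with 16 and 17 of 18 positive (1.33e-07 and 1.3e-08, or 0.168 and 0.144 estimated). Without Col_MS replicate 1 the 5 lists kept an adjusted p under 0.05 in both comparisons, the highest being 0.0121. Between wei8tar2 and kynurenine the iron-uptake list was called higher (0.0476, but 0.810 with an estimated correlation), which was lost without Col_MS replicate 1 (0.1), and the adjusted p of the other 4 lists lay between 0.492 and 0.900.

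Genes that set wei8tar2 apart from kynurenine, other than TAA1, were BGAL9, MRD1, HEI10, AT4G20690 and AT5G14840. Linkage to the mutated loci is argued against as the cause for all 5, since 2 of them, BGAL9 and AT5G14840, lie on chromosomes that hold neither TAA1 nor TAR2. For the other 3 it stays open, the nearest being AT4G20690 at 1.63 Mb and MRD1 and HEI10 lying at 6.64 Mb, because no value here gives the length of a segment that the line may have carried along with the mutations. Within 1 Mb of TAA1 or TAR2 lay 8 of 225 other genes called in wei8tar2, or 3.56%, against 4.27% of tested genes (Fisher's exact p = 0.74). These 3 genes lie outside that window, so the test does not decide for them. A gain of copies of the region of MRD1 and HEI10 would raise its neighbours, but their median log2 fold change in wei8tar2 was -0.37. A sequence or epigenetic variant carried by the line may account for BGAL9, MRD1 and HEI10 and stays open, as do effects of the mutations that kynurenine lacks; neither was tested.

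Col_MS replicate 1 stood apart from the other libraries. A bias by gene length or GC content as the whole reason is argued against, because a trend on both explained 5.92% of the variance of the log2 ratio of the Col_MS libraries and the genes more than 2-fold apart numbered 1085 before and 1048 after its removal. A part in the gap stays open. The Spearman correlation of that ratio with gene length was 0.32, against 0.10 between the Col_Kyn and -0.05 between the wei8tar2_MS libraries. A few genes taking most of the reads is argued against by the share of the 10 most counted genes, 7.34%, within the 6.97% to 8.12% of the other libraries. Seedlings less advanced in the use of their seed reserves may have contributed, as the reserve list had the highest median log2 ratio of the 23 lists, 1.25, followed by heat shock genes at 1.06. A gap in the reserve list was not particular to Col_MS, however. Its medians against the mean of the 6 libraries were 1.42 and 0.16 in Col_MS, -0.24 and -1.43 in Col_Kyn, and 0.91 and 0.26 in wei8tar2_MS. Whether stress, as in the camalexin and heat shock genes, also differed is open, and no explanation from the design was tested, because the labels give both libraries the same description.

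Root hair, root meristem and cell cycle lists were called lower with kynurenine, and the first and last also in wei8tar2, by camera with the preset correlation alone (adjusted p = 0.795, 0.746 and 0.746, and 0.810 and 0.810, with an estimated correlation). A smaller share of root RNA would lower the mature root tissue markers, of which 16 and 17 of 18 were positive, with medians up to 0.57. Of these edgeR called 3 and 1, the list test had an adjusted p of 0.168 and 0.144 with an estimated correlation, and a few members had been seen to rise before the list was written. Root genes outside that list went both ways. AGP30, BGLU21, BGLU34 and BGLU35 fell in both comparisons, and IRT1 rose in wei8tar2. Whether the share of root RNA differed can therefore not be decided from this list. Without Col_MS replicate 2 the root hair list in wei8tar2 was not called (0.176). A change of growth at the root tip tied to IAA synthesis, which the design names through the compound and the mutations, may underlie these values but stays untested, as does an effect of kynurenine apart from IAA.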
